A study of Mus musculus with 2 samples.

How the data were processed

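H3K4me1 ChIP-seq peaks of embryonic lung were analysed in 2 libraries, which the labels give as biological replicates from separate pools of embryos. Per the file descriptions deposited with each library, its peaks were derived from its own filtered mm10 alignments and 2 control files. The authors also made a pooled list from both alignments with the controls, and a replicated list from the library lists and the pooled list. The aligner, the peak caller and the rule of replication are not given in the sources used here. In the authors' narrowPeak lists, column 7 is the fold enrichment of a peak over control, a ratio. Columns 8 and 9 hold the −log10 of the p-value and of the q-value of each peak, as deposited. Folds and p-values served only to describe, rank or filter peaks within their list. The lists are lenient: −log10 p started at 2.11 in replicate 1 and 2.00 in replicate 2, and 53.6% and 54.9% of the peaks had a −log10 q of at least 2. A weakly enriched region can therefore be listed in 1 library and missing from the other. Reads, control tracks and signal tracks were not used here, and depth is unknown, so no interval that needs depth is given.

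Coordinates are on mm10 (GRCm38), 1-based. Sequence, gaps and repeats came from GRCm38 and genes from GENCODE release M21, on chromosomes 1 to 19, X and Y. Each of the 21829 protein-coding genes was represented by the TSS of its longest protein-coding transcript. Positions of domains and peaks were described with all protein-coding transcripts. Promoters were the 1 kb either side of any such TSS, and bases were assigned to promoters, then exons, then introns, then intergenic sequence. The CpG ratio (observed over expected) was taken in the 1 kb around the TSS and split at its median of 0.569.

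A peak counted as shared when at least 50% of its length lay under peaks of the other library. The Jaccard index was set against 100 random placements of the peaks of replicate 1 within the ungapped chromosomes. Gene coverage was the percent of the 20 kb either side of the TSS under peaks. The median of each of 21 gene lists, over the mean of the libraries, was ranked among 10000 random lists of as many genes drawn from the same 10 bins of gene length. A list was called above or below random at the 97.5th or 2.5th percentile. Random lists could hold any protein-coding gene, including the 948 X-linked genes and the 1463 receptor genes, which had little coverage. This can lower the random medians and raise the percentile of lists without such genes. All 465 places on the lists other than the receptors were found in the annotation. The lists were distal lung epithelium, proximal airway epithelium, lung mesenchyme, smooth muscle and pericyte, endothelium, mesothelium, blood and immune, neural crest and airway neurons, skeletal muscle, cardiac muscle, liver, pancreas and intestine, kidney, brain, limb and skeleton, pluripotency and germ line, anterior and posterior Hox genes, signalling of lung branching, housekeeping, and olfactory and vomeronasal receptors.

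For sequence words, up to 20000 peaks per library with the best p-value and over 2.5 kb from any TSS were used. Occurrences on either strand in their central 500 bp were divided by those in as many windows outside peaks on the same chromosome, matched on GC content in bins of 2%. The libraries gave 19993 windows each. Values are means with SD over the 2 libraries. The median of a gene list is instead taken over the mean coverage of each gene, with the SD of the library medians, and can lie outside both of these. With a single group, no test between groups was possible, and the spread is between pools of embryos.

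The gene lists, words, thresholds, main measures and most alternatives were fixed before the data were examined. Named genes followed a rule fixed then: the 3 highest and the lowest member of each list, the 15 genes of highest coverage, the genes at the 15 longest domains, the 10 replicated peaks of highest fold, and the 5 genes differing most between libraries in each direction. The Hox spans, the reversed words and the distances between neighbouring start sites were added after values had been seen. Alternatives covered a −log10 q of at least 2, the 50000 best peaks, other overlap rules, windows, matching and joining gaps, the replicated and pooled lists, and leaving out each library.

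The calculations used Python with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and were tested on simulated data. With 49.9% of 105476 intervals kept in place, the overlap measure found 50.2% shared. Of 40 unrelated pairs of lists, 7.5% reached the smallest p-value that 20 placements allow, against a nominal 4.76%. Of 100 simulated lists of 25 genes, 5 passed the upper percentile with unchanged coverage, where 2.5 are due by chance, 45 with coverage multiplied by 2 and 77 with coverage multiplied by 3. A planted word at 2 times its rate was found at 2.02.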

Results

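The libraries map histone H3 monomethylated at lysine 4 (H3K4me1), a chromatin mark found at enhancers and on the flanks of active promoters, by ChIP-seq in lung of mouse embryos at day 14.5 of gestation. At this age the airway epithelium is branching into the surrounding mesenchyme. The series held 1 group of 2 libraries, each made from pooled embryos of both sexes. Replicate 1 came from 24 embryos and replicate 2 from 34. Replicate 1 had 105476 peaks covering 36.2 Mb, which is 1.37% of the ungapped genome, and replicate 2 had 126748 peaks covering 41.6 Mb, or 1.57%. Median peak width was 264.5 bp ± 13.4 and median fold enrichment over control was 3.26 ± 0.0338 (SD, n = 2). Peak lists hold no read counts, so the depth of either library is unknown. No condition was compared within the series. The questions were therefore which genes and regions carried the mark, and how far the libraries shared their peaks.

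Genes that direct lung branching and genes of the lung mesenchyme lay in heavily marked surroundings, below only the anterior Hox genes among the 21 lists. Coverage was measured as the percent of the 40 kb centred on a gene's transcription start site (TSS) that lay under peaks, and each list was set against 10000 random lists of as many genes matched on gene length. The 52 genes of lung branching signals had a median coverage of 6.92% ± 0.491 (SD of the library medians, 6.99% and 7.68%, n = 2), against 1.56% for random lists. The 37 mesenchymal genes reached 5.17% ± 0.760, against 1.5%. Both medians lay above all 10000 random medians. Among the branching signals, 51 of 52 genes had a replicated peak in the window, and 35 of 37 mesenchymal genes did. Of all protein-coding genes, 42.2% had none. These lists overlap: 17 of the branching genes and 11 of the mesenchymal genes also stand on another list.

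In the branching list, Rara, a retinoic acid receptor, had the highest coverage at 50.2% ± 1.43, followed by the receptor gene Notch1 at 37.3% ± 2.42 and by Smad7, an inhibitor of TGF-beta signalling, at 35.1% ± 3.51 (SD, n = 2). Fgf10, the mesenchymal growth factor that draws out the buds, was lowest, with no peak bases in replicate 1 and 1.91% in replicate 2. In the mesenchymal list, the Hedgehog receptor gene Ptch1 stood at 33.4% ± 6.42. The growth factor receptor gene Pdgfrb had 22.1% ± 3.42, and Axin2, a target of Wnt signalling, had 16.9% ± 3.04.

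Smooth muscle and pericyte genes, 18 in number, had a median coverage of 4.28% ± 0.320, at the 99.8th percentile of random lists. Their highest members were the pericyte gene Cspg4 at 15.6% ± 2.80, the Notch target Heyl at 9.67% ± 5.09 and the desmin gene Des at 9.38% ± 4.11. Mef2c was lowest at 0.232% ± 0.329. The 34 genes of distal lung epithelium had a median of 2.98% ± 0.445, at the 99.3rd percentile. Of these genes, 23 (67.6%) had a replicated peak in the window. That share sets them little apart, since 42.2% of all protein-coding genes had none and the rest did. The list fell just under the limit on 5 kb either side of the TSS (96.5), with the replicated list (97) and with the 50000 best peaks (97.4). Fgfr2, the receptor for Fgf10, led this list at 22.3% ± 0.626. Ager, a marker of the flat alveolar cells, had 13.5% ± 0.403 in a window it shares with Pbx2, whose TSS is 5.60 kb away, and Sftpc, which encodes surfactant protein C, had 11.9% ± 0.507. Lamp3 had no peak in its window in either library.

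Endothelial genes had a median of 2.95% over the gene means, at the 98.8th percentile, above the library medians of 2.75% and 2.26%. They were led by Notch1 and by the ETS factor genes Ets1 at 24.5% ± 0.136 and Fli1 at 14.9% ± 5.07. Tie1 had no peak in its window. The endothelial call was fragile: the list fell to the 84.8th percentile in replicate 2 alone, to the 55.8th on 5 kb either side of the TSS, to the 89.0th with the 50000 best peaks and to the 93.8th with the replicated list. It also fell under the limit at 50 kb, with equal peak numbers, with a −log10 q of at least 2 and with the pooled list. Housekeeping genes had a median of 2.82% over the gene means, below the library medians of 3.27% and 2.95%, at the 98.1st percentile, with Actb at 12.9% ± 0.120, Rplp0 at 9.83% ± 1.10 and Gapdh at 9.06% ± 1.28, and Emc7 lowest at 0.307% ± 0.202. Against random lists matched on the CpG ratio of the promoter, the housekeeping list was at the 84.4th percentile, and in replicate 2 alone it was at the 97.4th with length matching. With the 50000 best peaks it was at the 93.9th, and with a −log10 q of at least 2 it fell just short of the limit.

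The other lists of cell types that dissected lung can hold were within the central 95% of random lists. Proximal airway genes were at the 51.9th percentile with a median of 1.33% ± 0.384. Their highest members were the ciliated cell gene Tppp3 at 11.2% ± 0.877, the secretory cell gene Scgb1a1 at 8.61% ± 1.36 and Foxa3 at 4.82% ± 0.582, while Gmnc had no peak bases. Mesothelial genes were at the 40.3rd percentile, led by Rspo1 at 5.98% ± 0.774, Upk1b and Krt19, with Muc16 at 0%. Blood and immune genes had a low median of 0.591% ± 0.111 and were at the 11.5th percentile. Cd68, a macrophage gene, had the most at 6.28% ± 2.12, ahead of Nfe2 and Runx1, and the erythroid gene Alas2, on chromosome X, had none. Neural crest and airway neuron genes were at the 34.2nd percentile, and at the 46.7th and 63.3rd in the single libraries, with Ednrb at 8.79% ± 1.11, then Gfra1 and Dbh, and with the X-linked Plp1 at 0%. Cardiac genes were at the 65.0th percentile, with Myh7 at 7.89% ± 0.818, then Myl7 and Tnnt2, and no peak around Myh6.

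Skeletal muscle genes were at the 55th percentile, although Tnnt3 at 19.3% ± 2.02, Tnni2 at 18.5% ± 0.00530 and Mymk at 15.8% ± 0.331 ranked far above the genome median of 1.41%. The TSS of Tnnt3 lies 34.9 kb from that of Mrpl23, so their windows overlap. Myh3 had no peak in its window.

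Among genes of other organs, none of the lists left the central 95% of random lists with length matching except the chemosensory receptors. Apart from the receptors, the median was lowest in liver genes, at 0.475% ± 0.0354 and the 5.55th percentile, with 6 of 23 genes near a replicated peak. Nr1h4 had 4.57% ± 1.61, ahead of Proc and Apoa2, and Ahsg had none. Pluripotency and germ line genes were at the 7.50th percentile, and at the 15.8th and 13.3rd in the single libraries, with Stra8 at 4.42% ± 1.48, then Pou5f1 and Nanog, and Dazl at 0%. Brain genes were at the 18.5th, with Gad1 at 7.77% ± 0.523, then Hes5 and Slc17a7, and Barhl1 at 0%. Pancreas and intestine genes were at the 30.9th percentile, kidney genes at the 53.3rd and limb and skeleton genes at the 89.0th. Cdx1, an intestinal factor gene with 14.3% ± 0.893, shares its window with Pdgfrb, whose TSS is 9.0 kb away, and Cpa1 and Vil1 followed it, with Ins2 at 0%. Cdh16 led the kidney list at 9.80% ± 0.589, ahead of Wnt9b and Eya1, with Pax8 at 0%. In the limb list, Col2a1 had 10.1% ± 2.47, ahead of Prrx2 and Sp7, and Tbx15 was lowest at 0.232% ± 0.329.

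The 1463 olfactory and vomeronasal receptor genes had a median coverage of 0% in both libraries, below all 10000 random medians, and 1391 of them had no peak in the window in either library. Olfr71 had the most, at 5.21% ± 0.258, followed by Olfr750 and Olfr455, and Olfr1 had none. Matched on the CpG ratio, the receptors were at the 50th percentile, because lists of such CpG-poor genes also had a median of 0. Those random lists could hold the receptors themselves, and a tie at 0 cannot tell the receptors from other CpG-poor genes. With that matching, brain genes at the 0.22nd percentile, pluripotency genes at the 1.52nd and posterior Hox genes at the 2.35th fell below the central 95% of random lists. The percentiles describe these libraries, since genes are not replicates.

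**Figure D1:**
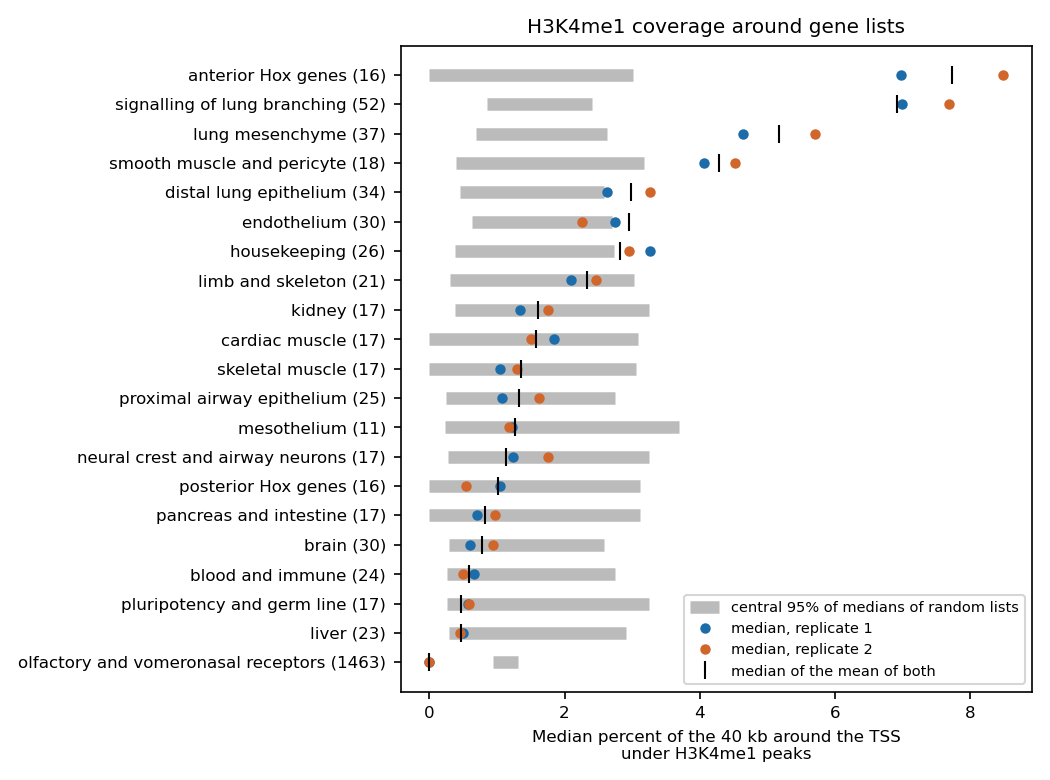
Median percent of the 40 kb around the TSS under H3K4me1 peaks (x axis) for each of the 21 gene lists (y axis, number of genes in brackets). Blue and orange points are the library medians, black marks the median of the mean of both libraries, and grey bars the central 95% of the medians of 10000 length-matched random lists; anterior Hox, branching and mesenchymal genes stand right of their bars at 7.73%, 6.92% and 5.17%.

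Hox genes, which set position along the body axis, differed by their place in the clusters. The 16 anterior genes had a median coverage of 7.73% ± 1.07, above all 10000 random lists, with Hoxb2 at 16.1% ± 2.05, Hoxa4 at 15.5% ± 0.861 and Hoxb3 at 14.6% ± 3.23, and Hoxd3 lowest at 0.892% ± 0.626. The 16 posterior genes had a median of 1.02% ± 0.355, at the 55.2nd percentile, with Hoxa9 at 2.55% ± 1.41, Hoxd10 at 1.80% ± 0.894 and Hoxd12 at 1.68% ± 0.824, and Hoxc13 at 0%. Within the HoxA cluster (mm10 chromosome 6), the span of the anterior genes, 52155590 to 52213336, was 16.9% ± 1.16 covered. It ends with the long annotation of Hoxa3 and takes in Hoxa6. The span from Hoxa9 to Hoxa13, 52223100 to 52260880, was 0.529% ± 0.749 covered, with no peak in replicate 2. HoxB (chromosome 11) had 13.6% ± 0.579 over its anterior span and 0.122% ± 0.172 over its posterior span (SD, n = 2). HoxC and HoxD had little on either side, at 1.13% and 0.565% for HoxC and 2.20% and 1.74% for HoxD, where the difference in HoxD had opposite signs in the libraries.

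On average over the libraries, the anterior span was higher in all 4 clusters, a comparison chosen after the data were seen, by 7.71 points on average, with an exact two-sided sign-flip permutation p of 0.125, the smallest that 4 clusters allow. Neighbouring Hox genes share windows and the HoxC spans overlap, so the genes are not independent.

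**Figure D2:**
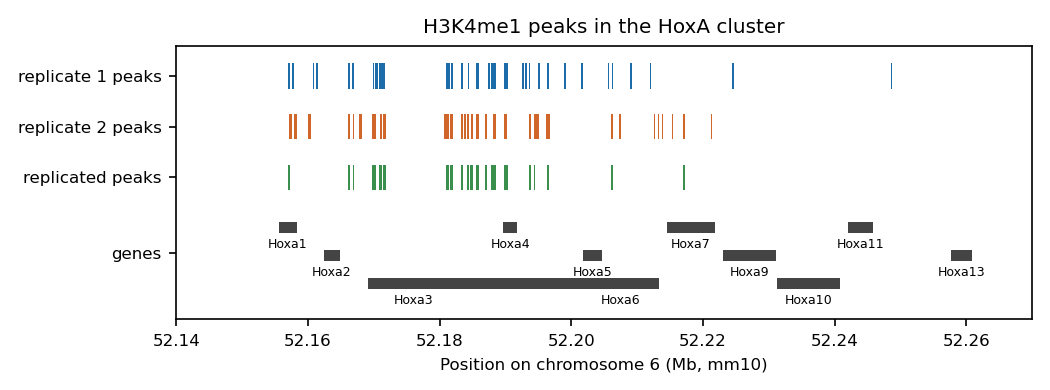
Map of the HoxA cluster on mm10 chromosome 6 (x axis, position in Mb), with peaks of replicate 1 (blue), of replicate 2 (orange) and of the replicated list (green) above the annotated Hoxa genes (grey). Peaks gather in the anterior part, from the start of Hoxa1 to the end of the Hoxa3 annotation, where 16.9% of bases were covered, and thin out from Hoxa9 to Hoxa13, where 0.529% were.

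Across all 21829 protein-coding genes, Rara (chromosome 11, TSS 98937718) had the highest coverage. Btg2, which slows cell division, followed at 42.3% ± 5.52, Elmsan1 at 41.3% ± 3.82, G430095P16Rik at 41.1% ± 6.95 and the chromatin reader gene Zmynd8 at 40.9% ± 0.659. Hspg2, which encodes the basement membrane proteoglycan perlecan, had 40.1% ± 3.48, Gse1 39.6% ± 0.232, Mrpl23 37.6% ± 3.99 and the matrix protein gene Tgfbi 37.6% ± 1.94 (SD, n = 2). Notch1, Bahcc1, Smad7, Zfp395, the circadian repressor gene Nr1d1 and the guidance factor gene Sema3f completed the top 15, down to 33.7% ± 4.13. In contrast, 5723 genes, or 26.2%, had no peak in the window in either library.

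The longest runs of closely spaced peaks lay over Smad7, Nfib, Bcl9l and Sh3pxd2a. Replicated peaks less than 1 kb apart were joined, which gave 37 domains of at least 10 kb. The longest spanned 20.5 kb of chromosome 18 (mm10, 75372526 to 75393043) inside Smad7, over introns and 217 exonic bases. An 18.8 kb domain on chromosome 4 (82432230 to 82451052) lay in an intron of Nfib, a transcription factor gene needed for lung maturation. Bcl9l, a coactivator of Wnt signalling, held a 17.6 kb domain across its start on chromosome 9 (44484375 to 44502019). An intron of Sh3pxd2a held 17 kb on chromosome 19 (47437458 to 47454484), and the Wnt inhibitor gene Nkd1 held 16.7 kb on chromosome 8 (88563874 to 88580551). The domain on chromosome 7 (142561165 to 142577296) overlapped no protein-coding gene, but covered the imprinted non-coding gene H19 and its microRNA gene Mir675, 27.4 kb from the nearest protein-coding TSS, that of Mrpl23. Actn4, Ptch1, Zfhx3, Smad6, Sept9, Rbpms, Pdlim2 and Lhfpl2 held the others among the 15 longest, and a 13.9 kb intergenic domain lay 5.19 kb from the TSS of Btg2. In each library, peaks covered at least 51.3% of every one of these 15 domains. The replicated list behind the domains was itself made with the library lists, so this is no independent measure of agreement. The count depended on the joining: 0 domains reached 10 kb without it and 544 did when gaps of up to 3 kb were bridged.

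The replicated peak of highest fold enrichment, 8.32, lay in an intron of Ptk7, a gene of planar cell polarity, on chromosome 17 (46617444 to 46622232). The peak next in order lay in an intron of Arid1b, a chromatin remodelling gene, on the same chromosome (5058961 to 5061246), with a fold of 8.10. Peaks in introns of Gse1 and of the corepressor gene Ncor2 followed at 8.08 and 8.01. Lasp1, Soga1, Rara, Phc2 and Sema3f held 5 more of the top 10, and an intergenic peak on chromosome 4 (155233297 to 155235340) lay 10.7 kb from the TSS of Ski, an inhibitor of TGF-beta signalling. These folds are the authors' own values for each peak.

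Start sites of genes with CpG-rich promoters were largely free of the mark and were flanked by it. At the 10914 promoters with a CpG ratio above the median, 1.81% ± 0.130 of start sites lay under a peak, against 10.9% ± 0.991 at 1 kb upstream and 20.3% ± 2.15 at 1 kb downstream (SD, n = 2). At the 10915 CpG-poor promoters the mark was highest close to the start, with 4.78% ± 0.635 at 0.5 kb upstream, 4.57% ± 0.220 at the TSS and 4.97% ± 0.0972 at 0.5 kb downstream, against 1.82% ± 0.104 at 2 kb upstream and 2.45% ± 0.214 at 2 kb downstream. The share at the TSS minus the mean share at 2 kb was -6.04 points ± 0.962 in CpG-rich and 2.43 points ± 0.0615 in CpG-poor promoters, and over all genes it was -1.8 points ± 0.450. Each of these differences was larger than the spread between the libraries and had the same sign in both. Downstream of CpG-rich starts, the share was highest at 1.1 kb in each library, at 19.5% in replicate 1 and 23.1% in replicate 2.

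**Figure D3:**
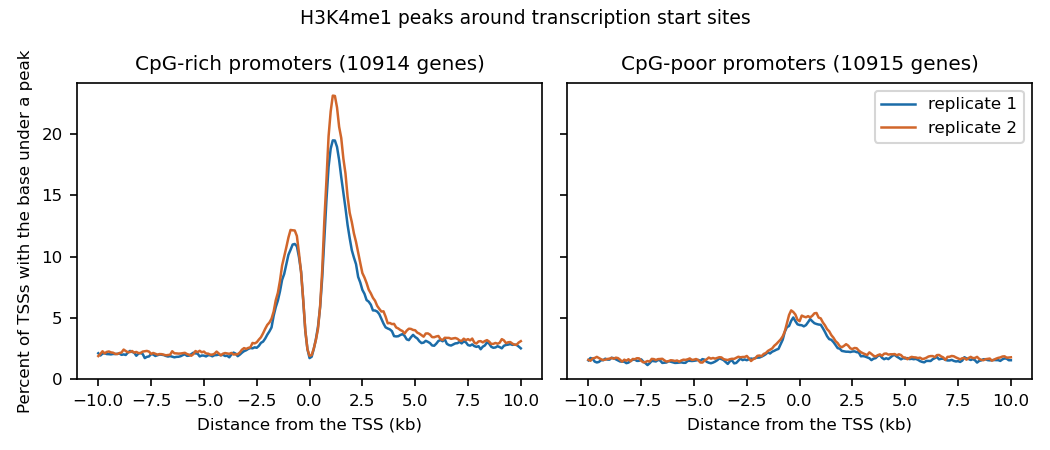
Percent of transcription start sites with the base at a given distance under an H3K4me1 peak (y axis) against the distance in kb (x axis, positive downstream), for CpG-rich promoters (left) and CpG-poor promoters (right), in replicate 1 (blue) and replicate 2 (orange). CpG-rich starts drop to 1.81% between an upstream flank that reaches 11% and 12.2% in the libraries and a downstream flank that reaches 19.5% and 23.1%, while CpG-poor starts have 4.57% and similar values at 0.5 kb on either side.

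Most marked bases lay in introns and between genes. Introns held 51.7% ± 0.728 of peak bases, 1.5-fold their share of the ungapped genome, and intergenic sequence held 33.9% ± 0.429, or 0.563-fold. Promoters, taken as 1 kb either side of a protein-coding TSS, held 10.6% ± 0.257, which was 4.33-fold their share, and other exonic bases held 3.86% ± 0.0423, or 1.28-fold (SD, n = 2). Of the 63253 replicated peaks, 11.9% lay within 1 kb of a TSS, 26.8% from 1 to 10 kb, 45.1% from 10 to 100 kb and 16.2% farther, with a median distance of 19.5 kb.

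Distal peaks were rich in the binding word of forkhead factors, the family of Foxa1, Foxa2 and Foxf1. TGTTTAC was 1.75-fold ± 0.0779 as frequent in the central 500 bp of peaks over 2.5 kb from any TSS as in GC-matched windows outside peaks. The words of basic helix-loop-helix factors (CAGCTG), GATA factors (AGATAAG), SP and KLF factors and MEF2 factors were 1.36-fold ± 0.0148, 1.35-fold ± 0.00353, 1.36-fold ± 0.0467 and 1.27-fold ± 0.0297 as frequent. The palindromic nuclear factor I site was rare, with 44 sites in each library against 12 and 5 in the matched windows. T-box words were less frequent in peaks, at 0.742-fold ± 0.0280. The words of POU, HNF4, NKX2-1, ETS, AP-1, TEAD and SOX factors lay between 1.06-fold and 1.18-fold.

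As a control chosen after the data were seen, each word was also read backwards, which keeps its base composition. Backwards, the forkhead word was at 1.22-fold, the helix-loop-helix word at 0.977-fold, the GATA word at 0.865-fold and the MEF2 word at 1.14-fold. The NKX2-1 word, at 1.17-fold ± 0.00141, and the SOX word, at 1.06-fold ± 0.00151, were no more frequent than their reversed forms at 1.23-fold and 1.18-fold. The POU, HNF4, TEAD, ETS and AP-1 words were at 1.18-fold, 1.18-fold, 1.12-fold, 1.16-fold and 1.13-fold. Their reversed forms were lower, at 0.856-fold, 0.937-fold, 0.944-fold, 1.04-fold and 1.07-fold. The reversed T-box word was at 0.926-fold. The SP and KLF word reads the same backwards and the reversed nuclear factor I site gave no ratio. Reading backwards does not keep CpG pairs: the reversed helix-loop-helix word, GTCGAC, holds a CpG that CAGCTG lacks. The SP and KLF word, GGGCGGG, also holds a CpG, and the windows were matched on GC content but not on the CpG ratio.

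The libraries marked largely the same gene neighbourhoods but shared fewer single peaks. Igf2r, an imprinted gene, differed most between them, with 19.5% in replicate 1 and 32.8% in replicate 2. Clcf1, AC109138.7 and Pold4, whose windows overlap on chromosome 19, and Rasl11b were also higher in replicate 2, with Clcf1 at 9.83% and 21.8% and Rasl11b at 23.6% and 35.5%. Map3k20 was the gene with the largest excess in replicate 1, at 12.3% against 5.34%, followed by the neighbours 1110002E22Rik and Gm5105, then Rassf2 and AI413582. Across the 21829 genes, coverage in the libraries had a Pearson correlation of 0.933 and a Spearman correlation of 0.884, with genes not being independent replicates.

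Base by base, the peak lists had a Jaccard index of 0.256. Random placements of 1 list within its chromosomes gave 0.00833 ± 0.000170 (100 placements), and the one-sided permutation p of 0.0099 is the smallest that 100 placements can give. The placements were uniform over the ungapped sequence, repeats included, so the p-value does not say how closely the pools agree. At least 50% of the length was covered by the other library's peaks for 40.2% of replicate 1 peaks (95% Wilson interval 39.9 to 40.5) and for 33.3% of replicate 2 peaks (33.1 to 33.6). These intervals cover counting error only. Counting any overlap of 1 bp, the shares were 54.6% and 46.1%. Strong peaks were shared more often. Among the 10% with the best p-value, 72.0% of replicate 1 peaks and 65.5% of replicate 2 peaks were shared, against 26.9% and 19.3% among the weakest 10%.

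All 63253 replicated peaks had the coordinates of a pooled peak, and they made up 53.3% of the 118707 pooled peaks (95% Wilson interval 53.0 to 53.6). Replicated peaks were wider, with a median of 417 bp against 227 bp for the other pooled peaks, and had a higher median fold, 3.41 against 2.78. Of the replicated peaks, 49756 had a peak in each library that overlapped by at least 50% of either peak, and 13497 did not meet that condition. A replicated peak need not be seen in both libraries, since 12405 touched a peak of only 1 library and 154 of neither. Among all pooled peaks, 8420, or 7.09%, touched no peak of either library, with those 154 included.

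Chromosome X carried far less of the mark than any autosome. Peaks covered 0.0620% of X in replicate 1 and 0.0843% in replicate 2, against 2.36% and 2.66% of chromosome 11, the most covered autosome in each library. The least covered autosome was chromosome 14 in replicate 1, at 1.13%, and chromosome 3 in replicate 2, at 1.31%. Relative to the median autosome, X had a coverage of 0.0463 ± 0.00557 (SD, n = 2). Replicate 1 had 377 peaks on X and replicate 2 had 533. Of these, 18.0% and 12.2% were shared, against 40.3% and 33.4% of autosomal peaks, and the replicated list held 148 peaks on X. No list held a peak on Y, where 96.3% of the sequence is annotated as repeat, against 46.8% of X. Reads may not be placed in repeats, but the part of Y outside them held no peak either, and no cause was tested. Around the 948 X-linked genes, mean coverage was 0.0488 of that around autosomal genes matched on length and neighbouring start sites in replicate 1, and 0.0701 in replicate 2.

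**Figure D4:**
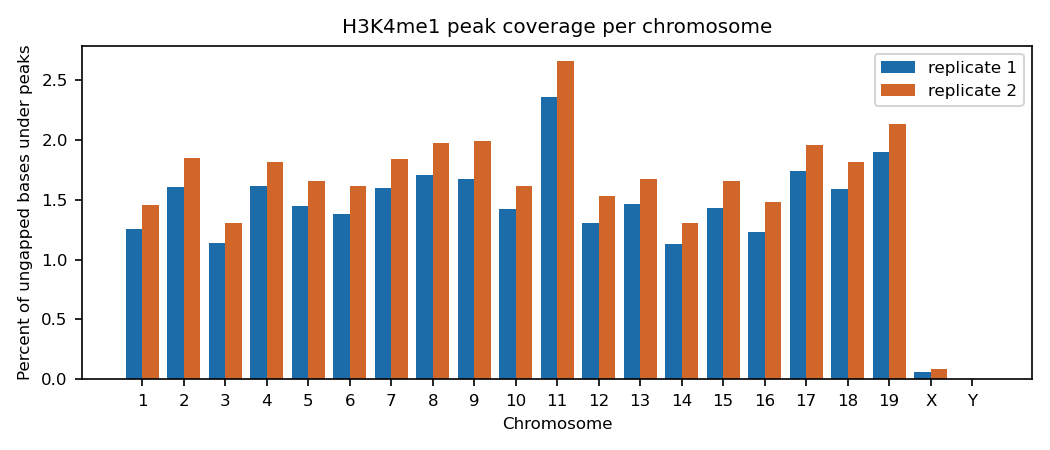
Percent of the ungapped bases of each chromosome under H3K4me1 peaks (y axis) by chromosome (x axis), in replicate 1 (blue bars) and replicate 2 (orange bars). Chromosome 11 is highest at 2.36% and 2.66%, X has 0.0620% and 0.0843%, and Y, which is mostly repeat sequence, has none.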

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

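Among the alternatives, 4 were chosen after seeing the data: matching on the CpG ratio, shifting the whole peak list, equalising peak numbers and dividing by the length outside repeats. The cause of each shift was not tested unless the setting itself gives it. Over the main results, 42 values stayed within a tolerance, which was 1.5 times for counts and the SD or interval for most others, and 20 left it. A fall from 7 lists above random lists to 5 or 6 counts as within it. With 2 libraries, either library alone always lies within the SD of their mean. For measures judged by the SD, leaving out a library therefore could not count as a shift. The Jaccard index was judged only against random placements, and shifting the list leaves the index itself unchanged. The 42 thus include values that could not have left the tolerance. Single lists were judged only by whether their call above or below random lists held, and single words by the SD. On these terms 256 values were unchanged, 19 word values left the SD, 16 list calls were lost and 3 were gained. An uncalled list could therefore shift far and still count as unchanged, as kidney genes did from the 53.3rd to the 6.68th percentile on 5 kb either side. No list called above or below random lists went to the opposite side. Matched on the CpG ratio, the uncalled posterior Hox genes went from the 55.2nd percentile to a call at the 2.35th, and blood and immune genes from the 11.5th to the 70.4th. With a −log10 q of at least 2, a library had 63092.5 peaks on average, shared shares were 37.7% and 30.1%, 78.9% of pooled peaks were replicated, 22 domains remained over 10 kb, and X stood at 0.0350 of the median autosome. With the 50000 best peaks, shared shares were 33.3% and 31.9%, the TSS difference was -1.29 points, and 4 lists instead of 7 lay above random lists. Sharing by 1 bp gave 54.6% and 46.1%, and by 50% of both peaks 26.7% and 22.2%. Promoters of 2.5 kb either side held 21% of peak bases. Domains numbered 0 without joining, 544 over gaps of 3 kb and 97 from pooled peaks. Matched on the CpG ratio, 3 lists lay below random lists. With all peak bases divided by the chromosome length outside repeats, X stood at 0.0581 of the median autosome.

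Leaving out a library gave 105476 to 126748 peaks, a promoter share of 10.4% to 10.7%, a TSS difference of -2.12 to -1.49 points, 5 to 7 lists above and 1 below random lists, 6 to 7 frequent words and an X ratio of 0.0424 to 0.0502. Distal epithelium fell just under the limit at 5 kb (96.5), with the replicated list (97) and with the 50000 best peaks (97.4), and the endothelial list ranged from the 55.8th to the 99.7th percentile. No paired analysis was possible because the series holds 1 group and compares no conditions. Unknown depth limits every statement that a region lacks the mark.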

Other observations

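Gene families also differed in coverage, though some members, such as Smad7, Tbx15 and Col2a1, stand on the fixed lists too. Autosomal genes were grouped by the letters of their symbols before the number, with at least 8 members at 8 separate places, and this grouping was made after the data were seen. Of 307 such families, 42 had a median above and 28 below the central 95% of 10000 length-matched random lists, against 7.67 on each side by chance. The Smad genes, which carry TGF-beta and BMP signals, had a median of 6.58% of their 40 kb windows under peaks against 1.71% for random lists. All 8 had a replicated peak in the window, where 42.2% of all protein-coding genes had none. Sema genes, which encode guidance factors, had 4.91% against 1.56%, led by Sema3f, Sema3b and Sema4c. Tspan genes of the tetraspanins had 6.14% and integrin alpha genes (Itga) 4.55%, led by Itga3, Itga6 and Itga9. Tbx genes stood at 3.91% with Tbx2 and Tbx3 highest, and collagen genes (Col) at 2.61% with Col4a2, Col4a1 and Col1a1 highest. These are a selection, and the 42 were not confined to signalling or matrix genes. Ppp genes had 3.36% against 1.49%, Tmem genes 2.51% against 1.36% and Rps genes 3.02% against 0.885%. Matching was on gene length only and not on the CpG ratio.

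Other families were low, again with matching on gene length only and not on the CpG ratio. The 100 Cyp genes had a median of 0% against 1.53% for random lists, although Cyp1b1 and the retinoic acid-degrading Cyp26b1 led them. The glucuronosyltransferase genes (Ugt), the sulfotransferase genes (Sult), the Serpinb genes and the Tmprss genes also had medians of 0%. The 385 zinc finger genes named Zfp had 0.979% against 1.55%, below all random lists. Members of a family can lie close together and share windows, so these ranks describe the libraries only.

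The following patterns were weighed, and the tests of CpG-rich promoters, of the cell type mix as run here, of strong X peaks and of other thresholds were chosen only after the result was seen. The near absence of peaks from chromosome X came first. Repeats were set aside by dividing all peak bases, those inside repeats included, by the chromosome length outside repeats. X then still had at most 0.0789 of the value of the lowest autosome. Low gene density was set aside by matched genes, where X genes had at most 0.0701 of the coverage of autosomal genes. A biological candidate was a single active X in each cell, which could halve enrichment on X and push weak peaks under the threshold, but at the threshold fixed beforehand, the 5th percentile of X folds, halved autosomal folds left 0.442 of the X peaks seen, beyond the factor of 2 allowed. Other thresholds moved this ratio from 0.304 to 2.64, so strong peaks were also counted. Over the median fold of X peaks, 3.14 and 3.23, halving left 0.0682 and 0.0579 of the X peaks seen. Among shared peaks the cut was the median fold of shared X peaks, 3.18 and 3.52, and halving left 0.331 and 0.153. Exact halving of every fold thus left too few strong X peaks, though the comparison of shared peaks rested on 34 and 33 X peaks over the median. At the threshold fixed beforehand, factors of 0.561 in replicate 1 and 0.543 in replicate 2 would give the X peaks seen. Those factors were solved to give that count, so they do not support the cause. Halving left median folds of at most 2.84 and 2.79 at any threshold tried. The X peaks seen had medians of 3.14 and 3.23, near the autosomal 3.28 and 3.24. These medians argue against exact halving of every fold. A lower fold of another size was not compared with them and stays open, and fewer reads on X without lower folds were not tested.

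With 50% overlap required, most single peaks were not shared, while gene neighbourhoods were. Weak peaks near the threshold stay open as a cause: under that rule 65.5% of the strongest 10% of replicate 2 was shared, short of the 80% set beforehand, but counting any overlap 87.0% and 81.8% of the strongest 10% were, so the rule itself decided the outcome. Differently placed peak borders stay open: of the unshared peaks in the strongest 10%, 83.8% in replicate 1 and 78.2% in replicate 2 had a peak of the other library within 1 kb, against 9.61% and 8.76% with the list shifted at random, and the lower value just missed the condition of 80%. A different mix of cell types stays open too: with length-matched random lists, 7 of 21 gene lists differed between the libraries beyond the central 95% and 4 beyond the central 99%, but replicate 2 covered more bases in all, and after matching on mean coverage, a choice made on seeing this, only 1 did. That list is the posterior Hox genes, lower in replicate 2 by a median of 0.475 points.

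Housekeeping genes ranked high. CpG-rich promoters may account for it, as the list was at the 84.4th percentile among lists matched on the CpG ratio and at the 98.1st among length-matched ones. No biological explanation was tested.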
